A study of Mus musculus with 6 samples.

How the data were processed

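RNA sequencing of mouse bone marrow-derived macrophages was analysed from the expression table of the whole series, which holds 3 control libraries and 3 libraries of cells treated with lipopolysaccharide (LPS), all taken at 24 h. The values are TPM (transcript abundances scaled to a fixed total per library) as deposited by the authors, with 2 decimals, for 55736 genes, and each deposited library sums to 1000000 TPM within 1 TPM. The table also gives the authors' group means, which equal the means of the library values to within 3.3e-05 TPM, and 1723 of its rows carry no gene symbol, 322 of them loci named as assembled transcripts. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, with no role for any of them. The tool that gave the TPM values, the annotation release and the use of strand are not given in the sources used here. Of the gene identifiers, 52081 (93.4%) are in GENCODE release M21 of the GRCm38 assembly, from which coordinates were taken by identifier.

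The TPM values keep no read depth, so the depth of each library is unknown and no counting error or detection limit can be given. TPM also has a fixed total in every library, so a few genes that take a larger share lower the values of all others. An exact 0 can be a failed estimate. There are 25 genes, mostly pseudogenes and small RNAs, that are listed at 0 in 1 library while both others of its group give at least 10 TPM, and such a gene is only described as listed at 0. How reads shared by near-identical genes were divided is not given in the sources used here, so values of ferritin genes, mitochondrial genes with nuclear copies and closely related class I histocompatibility genes carry that doubt. The treatment text and the titles of the treated samples both give 200 ng/ml LPS, per the labels. The titles also carry the number 500, whose meaning is not given in the sources used here.

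Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 12440. The test was limma 3.58.1 (lmFit and eBayes with a trend, R 4.3.3) on log2(TPM + 1), LPS minus control, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a limit of 0.05. All adjusted p-values of genes in the text come from this test unless another is named. Changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. Levels are given as mean TPM ± SD of 3 libraries. Nothing in the labels says that libraries of a group come from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. With 3 against 3 libraries an exact two-sided permutation test of a single value cannot go below p = 0.1. In simulated data on 12440 genes, with the control means and a smoothed spread of these libraries, the test recovered 98.5% of genes changed by 0.5 on the log2 scale. It recovered 100% of those changed by 1 or by 2, with 5.24% of its calls false. Only 67, 67 and 66 genes were changed, all with a control mean of at least 3 on the log2(TPM + 1) scale. No shift shared by most genes was simulated. These shares therefore do not cover low genes or such a shift. In a second simulated set of the same kind the list test called the 1 list that was moved and 0 of 50 lists that were not. Genes were drawn independently there, so it cannot show how the list test behaves where members are correlated.

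Before the data were examined, 33 gene lists were fixed, from textbook knowledge of macrophages, of other cells that a marrow culture could hold and of RNA quality. They cover chemokines, chemokine receptors, inflammatory cytokines, classical and alternative activation, interferon-stimulated genes, NF-kB subunits with feedback inhibitors, pattern recognition, inflammasomes, antigen presentation by both classes, glycolysis, the TCA cycle with oxidative phosphorylation, NRF2 targets with itaconate and arginine metabolism, cholesterol synthesis, cholesterol efflux, eicosanoids, matrix remodelling with osteoclast genes, cell cycle, lysosome, macrophage identity, immediate early genes, 8 other cell types, mitochondrial mRNAs, ribosomal proteins and histones. For each list the members that rose and fell were counted, with adjustment over all tested genes and over the list alone. The 27 lists with at least 5 tested members were compared with all other tested genes by camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry accompanied it. Camera with an estimated correlation also takes its degrees of freedom from the 6 libraries and not from the genes, which raises p whatever the correlation. Summed TPM of the other-cell and quality lists was compared by an exact permutation test.

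The genes named in the text were set by a rule fixed at the same time, which gave 76 tested genes. It takes Ccl7 with the receptors Ccr1, Ccr2 and Ccr3. It adds the 6 largest rises and the 6 largest falls among called genes whose groups do not overlap, with a regular symbol and at least 10 TPM in the higher group. From each biology list it takes the pair with the smallest p and the called member with the smallest p that moved against the majority of the list, and from each other-cell list the member with the highest level. Nos2, Il1b, Il6, Tnf, Arg1 and Mrc1 complete it. Any other gene named was chosen after its value was seen and is marked so.

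The alternatives, fixed with the lists unless stated, were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 TPM, scaling by the median of ratios to a geometric mean library, upper-quartile scaling, quantile normalization, rescaling without mitochondrial and ribosomal protein genes, the replicate number as a block, eBayes without a trend or with robust variance, array weights, a test against a fold of 1.5, and leaving out each library in turn. Rescaling without Saa3 and Fth1 was chosen after seeing the data. Principal components and Spearman correlations of log2(TPM + 1) described the libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. KEGG and Gene Ontology terms were those annotated in the deposited table.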

Results

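Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages, the macrophages that grow out of marrow cells in culture. There were 3 control libraries and 3 libraries from cells given LPS, a glycolipid of the outer membrane of Gram-negative bacteria that activates Toll-like receptor 4. All were taken at 24 h. The treatment text and the titles of the treated samples give 200 ng/ml LPS, and the titles also carry the number 500, whose meaning is not stated. The study is concerned with the chemokine CCL7 in macrophage polarization and in arthritis, and the comparison made here asks which transcripts, Ccl7 among them, differ between LPS-treated and control macrophages. Values are TPM, whose read depth is unknown.

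After LPS most tested transcripts of the lists of chemokines, inflammatory cytokines and interferon-stimulated genes were higher, and those of the cell cycle list were lower on TPM as deposited. Saa3, an acute-phase serum amyloid, had 11 ± 2.63 TPM in control and 100091 ± 5882 TPM in LPS libraries (SD, n = 3 each). Lcn2, which binds bacterial siderophores, went from 0.227 ± 0.260 to 3199 ± 174 TPM, complement factor gene Cfb from 0.840 ± 0.724 to 3371 ± 39.4 TPM, haptoglobin gene Hp from 1.01 ± 0.839 to 1851 ± 14.2 TPM, Ccl5 from 6.88 ± 3.21 to 8273 ± 274 TPM and Il1b from 0.227 ± 0.0351 to 781 ± 15.6 TPM. The largest falls were in Stmn1, a microtubule regulator, from 663 ± 23.6 to 3.24 ± 0.287 TPM, in Hpgd, which inactivates prostaglandins, from 209 ± 12.9 to 0.35 ± 0.07 TPM, and in the mitotic genes Ube2c, Kif23, Birc5 and Cdca3, which had between 159 and 208 TPM in control and between 0.563 and 1.13 TPM in LPS libraries. Adjusted p-values of these 12 genes by limma lay between 5.95e-10 and 1.67e-07, and for each of them the libraries of the groups did not overlap.

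Of 12440 tested genes, limma called 9469 (76.1%) at an adjusted p under 0.05, 2028 higher and 7441 lower in LPS libraries. At least 2-fold changes made up 824 of the higher and 2685 of the lower calls. The groups did not overlap in 9782 genes (78.6%), where chance gives 10%. The median change of all tested genes was −0.44 on the log2 scale, so changes of groups are given below relative to that median. Scaling by the median of ratios, which moves the median to 0.00, called 4167 genes higher and 4181 lower, 1360 and 1471 of them at least 2-fold. All 2028 genes called higher on TPM as deposited were also called higher after that scaling. Of those called lower, 4181 were lower again and 491 were called higher. The scaling divides control libraries by 1.17 to 1.21 and LPS libraries by 0.83 to 0.86, so it can only raise a change. A higher call could therefore not turn and could hardly be lost, and only the lower calls were put to a test.

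**Figure D1:**
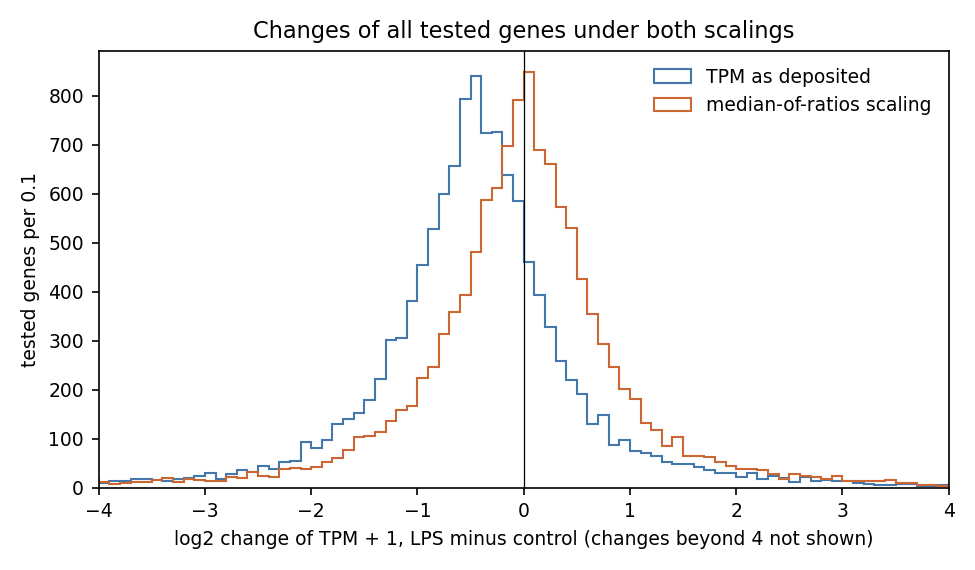
Histogram of the log2 change of TPM + 1 (LPS minus control, x axis) over the 12440 tested genes (y axis, genes per 0.1), for TPM as deposited and after median-of-ratios scaling. The bulk of genes lies below 0 for TPM as deposited, with a median of −0.44, and around 0 after scaling.

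The composition of the libraries differed between groups. Saa3 and Fth1 (ferritin heavy chain, named after its value was seen) together held 17.6% ± 0.497 of TPM in LPS and 2.02% ± 0.0964 in control libraries (SD, n = 3 each). The top 10 genes of a library held 27.2% ± 0.576 in LPS and 15.9% ± 0.426 in control libraries, and 11609 ± 29.8 against 12401 ± 29.3 genes reached 1 TPM. Spearman correlations lay between 0.983 and 0.987 within groups and between 0.826 and 0.838 across groups. The first principal component held 89.4% of the variance and separated the groups. On the second, with 3.56%, control library 2 stood apart from the other control libraries.

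Ccl7 encodes a monocyte-attracting chemokine (ENSMUSG00000035373; GRCm38 chromosome 11, 82045712 to 82047525, plus strand, 3 exons). Its transcript had 10.3, 13.8 and 8.15 TPM in the control libraries and 247, 254 and 257 TPM in the LPS libraries. The means, 10.7 ± 2.83 and 253 ± 5.06 TPM, differ 23.6-fold. The change on the log2(TPM + 1) scale was 4.46 (SE 0.16, limma adjusted p = 3.04e-07), and the exact two-sided permutation test of TPM gave p = 0.1, the smallest that 3 against 3 libraries allow. By rise, Ccl7 ranked 77 among all tested genes and 5 among the 18 tested chemokines, and by LPS level 9 among chemokines. Of the receptors that CCL7 is known to bind, Ccr1 rose from 15.1 ± 0.934 to 45.5 ± 5.52 TPM (adjusted p = 6.00e-06), while Ccr2 fell from 8.98 ± 0.802 to 0.487 ± 0.160 TPM (adjusted p = 1.11e-06) and Ccr3 from 5.75 ± 0.653 to 2.63 ± 0.306 TPM (adjusted p = 0.000287).

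Chemokine transcripts rose as a group. Of 18 tested members 14 rose, 3 fell and 1 did not pass, and the list's median lay 3.31 above that of all genes (log2; camera adjusted p = 4.51e-11). Besides Ccl5 and Ccl7, the monocyte chemoattractant Ccl2 rose from 49.6 ± 1.19 to 547 ± 26.3 TPM and the interferon-induced Cxcl10 from 3.95 ± 0.184 to 270 ± 35.1 TPM. Ccl6 fell from 115 ± 6.35 to 51.9 ± 1.57 TPM. After median-of-ratios scaling 15 members rose and 1 fell. With no filter on low values 16 of 26 members rose, 4 fell and 6 did not pass. The median then lay 0.90 above all genes (camera adjusted p = 4.83e-11). The 13 tested receptors for chemokines and related attractants parted, with 5 that rose and 8 that fell, or 5 and 6 after median-of-ratios scaling (camera adjusted p = 0.315). The median of that list lay 0.08 below that of all genes, while its mean and the direction of camera lay above. Camera turned down for these receptors after median-of-ratios scaling (adjusted p = 0.922) and under quantile normalization (adjusted p = 0.788). The formyl peptide receptor genes Fpr1 and Fpr2 rose from 0.737 ± 0.0961 to 628 ± 22 TPM and from 1.34 ± 0.447 to 513 ± 8.49 TPM. Markers of neutrophils, another marrow cell, moved with these groups: the list's 15 genes summed to 70.3 ± 2.75 TPM in control and 3432 ± 169 TPM in LPS libraries (exact permutation p = 0.1, BH-adjusted 0.183 over 11 sums), of which Lcn2 held 3199 TPM in LPS libraries. All 5 tested members rose (camera adjusted p = 7.95e-06). With no filter on low values 4 of 12 neutrophil genes rose and 8 did not pass. The median of the list then lay 0.12 above all genes (camera adjusted p = 0.00159).

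**Figure D2:**
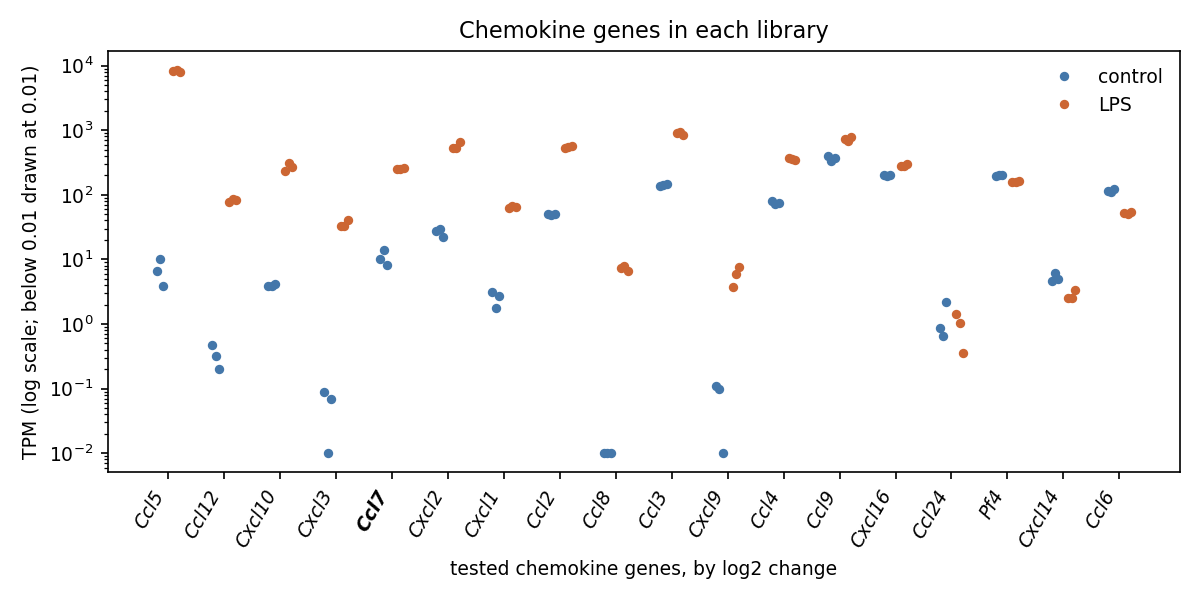
TPM (log axis) of the 18 tested chemokine genes in each library, ordered by log2 change; each point is 1 library, 3 control and 3 LPS per gene, and values below 0.01 are drawn at 0.01. Ccl7 lies between 8.15 and 13.8 TPM in control and between 247 and 257 TPM in LPS libraries.

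Inflammatory cytokine genes rose in 13 of 15 tested members, 1 fell and 1 did not pass (median 2.37 above all genes, camera adjusted p = 4.82e-11). With no filter on low values 14 of 20 rose, 1 fell and 5 did not pass. The median then lay 1.21 above all genes (camera adjusted p = 9.40e-13). Il1a rose from 0.0433 ± 0.0451 to 165 ± 8.76 TPM and Tnf from 23.9 ± 1.31 to 195 ± 9.15 TPM. Il6 stayed low in level, with 0, 0.0800 and 0 TPM in control and 3.05, 3.94 and 2.61 TPM in LPS libraries (log2 change 2.02, SE 0.15, adjusted p = 1.45e-05). Il15 fell from 27.2 ± 4.42 to 14.8 ± 1.65 TPM, a call lost under quantile normalization (adjusted p = 0.0635). The sum of the neutrophil list, 70.3 and 3432 TPM, moved with this list and with that of classical activation too. Lcn2 alone held 3199 TPM of that sum in LPS libraries.

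Markers of classical activation, the inflammatory state that LPS is known to induce, rose in 19 of 23 tested members and fell in 2, or in 3 adjusted over the list alone, with 20 and 1 after median-of-ratios scaling (median 3.07 above all genes, camera adjusted p = 1.07e-16). The ectoenzyme gene Cd38 rose from 0.0733 ± 0.0115 to 260 ± 7.61 TPM. Nos2, the inducible nitric oxide synthase, was listed at 0 in all 3 control libraries and at 8.37, 12.2 and 12.5 TPM in LPS libraries. Irf5 fell from 192 ± 2.93 to 116 ± 13.1 TPM. Of markers of alternative activation, the state linked to interleukin 4, 2 of 14 tested members rose, 9 fell and 3 did not pass, or 4 rose and 9 fell after median-of-ratios scaling. The median of the list lay 0.88 below that of all genes, and camera did not call it (adjusted p = 0.325). The mannose receptor gene Mrc1 fell from 172 ± 8.09 to 6.42 ± 1.46 TPM and the folate receptor gene Folr2 from 468 ± 19.4 to 47.0 ± 7.02 TPM. The arginase gene Arg1, a member of this list, rose from 0.447 ± 0.212 to 6.93 ± 1.01 TPM and the interleukin 4 receptor gene Il4ra from 41.3 ± 2.09 to 118 ± 12.5 TPM.

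All 40 tested interferon-stimulated genes rose (median 3.16 above all genes, camera adjusted p = 1.83e-35). Irf7, a transcription factor of the interferon response, rose from 28.4 ± 1.01 to 944 ± 39.7 TPM and Oasl1 from 2.60 ± 0.0651 to 151 ± 9.33 TPM. NF-kB subunits and feedback inhibitors rose in 23 of 27 tested members, 3 fell and 1 did not pass, or 25 rose and 0 fell after median-of-ratios scaling (median 1.78 above all genes, camera adjusted p = 7.88e-17). Socs3, an inhibitor of cytokine signalling, rose from 12.1 ± 0.399 to 376 ± 24.96 TPM and the interleukin 1 receptor antagonist Il1rn from 8.12 ± 0.571 to 261 ± 9.69 TPM. The subunit gene Rel fell from 15.2 ± 0.885 to 9.85 ± 0.524 TPM, a call lost after median-of-ratios scaling (adjusted p = 0.181, log2 change −0.12) and under quantile normalization (adjusted p = 0.722).

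Pattern recognition genes split evenly, with 13 of 27 tested members that rose, 13 that fell and 1 that did not pass, or 15 and 9 after median-of-ratios scaling (camera adjusted p = 0.00426, adjusted p = 0.242 with an estimated correlation). Camera also lost this call after median-of-ratios scaling (adjusted p = 0.0723) and under quantile normalization (adjusted p = 0.0595). With no filter on low values the median of the list relative to all genes was −0.093. The lectin receptor gene Clec4e rose from 19.4 ± 0.573 to 1349 ± 73.1 TPM and Tlr1 from 24.0 ± 0.648 to 110 ± 2.74 TPM. Tlr13 fell from 216 ± 9.74 to 84.1 ± 1.84 TPM. Inflammasome and lytic death genes rose in 12 of 22 tested members, 7 fell and 3 did not pass, or 16 rose and 5 fell after median-of-ratios scaling (camera adjusted p = 0.00163, adjusted p = 0.124 with an estimated correlation). The pyrin gene Mefv rose from 18.1 ± 0.287 to 84.3 ± 2.41 TPM and Nlrp1b fell from 23.6 ± 2.46 to 3.53 ± 0.321 TPM.

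Antigen presentation by class I molecules rose in all 22 tested genes (median 1.79 above all genes, camera adjusted p = 4.94e-20). H2-T22 rose from 64.6 ± 1.81 to 368 ± 14.2 TPM and H2-Q7 from 2.63 ± 0.540 to 145 ± 13.6 TPM, both with near-identical relatives that may share reads. Class II presentation and costimulation genes were mixed, with 6 of 15 that rose, 5 that fell and 4 that did not pass, or 9 and 3 after median-of-ratios scaling (median 0.60 above all genes, camera adjusted p = 0.00800, adjusted p = 0.124 with an estimated correlation and 0.0833 under quantile normalization). H2-Ab1 rose from 103 ± 3.21 to 632 ± 12.4 TPM. The checkpoint ligand gene Cd274 rose from 14.6 ± 0.949 to 165 ± 5.91 TPM. Ciita, the class II transactivator, fell from 7.02 ± 0.468 to 0.490 ± 0.0529 TPM. Dendritic cell markers, a cell type that presents antigen, summed to 16.9 ± 2.65 TPM in control and 18.6 ± 2.44 TPM in LPS libraries (exact permutation p = 0.5). Of their 3 tested genes 1 rose. Itgax had 10.95 ± 2.11 and 8.57 ± 0.973 TPM without passing the test (adjusted p = 0.0819). Its log2 change turned from −0.31 to 0.14 after median-of-ratios scaling. It passed without control library 1 (adjusted p = 0.0359) and with mitochondrial and ribosomal protein genes left out (adjusted p = 0.0350). It also passed with the replicate number as a block (adjusted p = 0.0381).

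Glycolysis and HIF-1 target genes rose in 20 of 27 tested members, 5 fell and 2 did not pass, or 23 rose and 3 fell after median-of-ratios scaling (median 1.14 above all genes, camera adjusted p = 1.06e-10, adjusted p = 0.162 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 44.3 ± 1.38 to 256 ± 9.65 TPM and the phosphofructokinase gene Pfkl from 26.9 ± 0.595 to 119 ± 2.20 TPM. Aldoc fell from 41.7 ± 0.864 to 12.2 ± 0.534 TPM. For the nuclear genes of the TCA cycle and oxidative phosphorylation the direction depended on scaling: 9 of 35 rose and 15 fell on TPM as deposited, and 27 rose and 3 fell after median-of-ratios scaling. Their median lay 0.32 above that of all genes (camera adjusted p = 0.0811), or at −0.022 from it with no filter on low values. Camera called the list higher after median-of-ratios scaling (adjusted p = 4.79e-05), after upper-quartile scaling (adjusted p = 0.000142) and with Saa3 and Fth1 left out (adjusted p = 0.000907). On TPM as deposited it had an adjusted p = 0.192 with an estimated correlation. The direction of Idh3g, which fell from 149 ± 8.65 to 74.9 ± 3.19 TPM, and of Mdh2, which rose from 156 ± 6.61 to 279 ± 10.6 TPM, held under both scales. Median-of-ratios scaling can only raise a change here, so it tested the fall of Idh3g and not the rise of Mdh2. Mitochondrially encoded mRNAs summed to 50004 ± 2323 TPM in control and 21657 ± 697 TPM in LPS libraries (exact permutation p = 0.1, BH-adjusted 0.183), and 12 of 13 fell (camera adjusted p = 0.0153, adjusted p = 0.374 with an estimated correlation). Ribosomal protein genes summed to 78915 ± 4753 and 48702 ± 2310 TPM (exact permutation p = 0.1), and 75 of 79 fell and 1 rose on TPM as deposited against 31 that fell and 6 that rose after median-of-ratios scaling (camera adjusted p = 8.78e-05, adjusted p = 0.528 with an estimated correlation).

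Among NRF2 targets and genes of itaconate and arginine metabolism 12 of 25 rose, 12 fell and 1 did not pass, or 15 rose and 6 fell after median-of-ratios scaling (median 0.70 above all genes, camera adjusted p = 0.000509, lost under quantile normalization with 0.0595). Acod1, which makes itaconate, rose from 1.89 ± 0.522 to 1475 ± 70.1 TPM and the mitochondrial superoxide dismutase gene Sod2 from 96.2 ± 8.41 to 3949 ± 57.5 TPM. The metallothionein gene Mt1 fell from 394 ± 17.1 to 120 ± 9.77 TPM.

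Cholesterol synthesis and uptake genes fell in 21 of 23 tested members and 2 did not pass, or fell in 16 and rose in 3 after median-of-ratios scaling (median 0.59 below all genes, camera adjusted p = 0.01005, adjusted p = 0.374 with an estimated correlation). Idi1, of the mevalonate pathway, fell from 27.8 ± 2.44 to 7.74 ± 0.679 TPM and the sterol transporter gene Stard4 from 23.3 ± 2.32 to 6.94 ± 0.354 TPM. Of cholesterol efflux and LXR target genes 4 of 17 rose and 13 fell, or 4 and 9 after median-of-ratios scaling (camera adjusted p = 0.325, but 0.0242 under quantile normalization, and adjusted p = 0.528 on TPM as deposited with an estimated correlation). The lipoprotein lipase gene Lpl fell from 2151 ± 164 to 265 ± 4.63 TPM and Nceh1, which hydrolyses cholesteryl esters, from 141 ± 4.37 to 33.6 ± 0.928 TPM. Nr1h3, which encodes LXR alpha, rose from 16.8 ± 3.06 to 120 ± 4.49 TPM. Lysosomal genes fell in 24 of 31 tested members, 5 rose and 2 did not pass, with 17 that fell and 9 that rose after median-of-ratios scaling (camera adjusted p = 0.0617). Camera called the list lower without LPS library 3 (adjusted p = 0.0498), with no filter on low values (adjusted p = 0.000896), under quantile normalization (adjusted p = 0.000798) and without mitochondrial and ribosomal protein genes (adjusted p = 0.0468). On TPM as deposited the lysosome list had an adjusted p = 0.528 with an estimated correlation. The lysosomal acid lipase gene Lipa fell from 929 ± 52.9 to 102 ± 2.50 TPM and cathepsin gene Ctsz rose from 939 ± 27.0 to 2859 ± 95.4 TPM.

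Genes of eicosanoid synthesis and receptors changed in both directions, 8 of 18 up and 10 down, or 9 and 8 after median-of-ratios scaling (camera adjusted p = 0.269). Ptges, the inducible prostaglandin E synthase, rose from 0.997 ± 0.607 to 369 ± 6.90 TPM, against the fall of Hpgd given above. Of matrix remodelling and osteoclast genes, which bear on joint tissue, 8 of 24 rose, 10 fell and 6 did not pass, or 14 rose and 9 fell after median-of-ratios scaling (camera adjusted p = 0.0812). Acp5, the tartrate-resistant acid phosphatase of osteoclasts and macrophages, rose from 13.6 ± 1.23 to 312 ± 3.25 TPM and the membrane metalloproteinase gene Mmp14 from 27.9 ± 3.65 to 901 ± 73.3 TPM. Stromal markers summed to 15.6 ± 1.98 TPM in control and 14.9 ± 1.17 TPM in LPS libraries (exact permutation p = 0.6) and chondrocyte markers to 4.68 ± 2.56 and 6.36 ± 2.95 TPM (exact permutation p = 0.5). Of 6 tested stromal genes 2 rose and 1 fell (camera adjusted p = 0.171), the latter Bgn from 4.16 ± 0.508 to 2.82 ± 0.703 TPM, whose log2 change of −0.44 (adjusted p = 0.0329) turned to 0.16 under quantile normalization. Its call was also lost without control library 1 (adjusted p = 0.0984), control library 3 (0.0780), LPS library 2 (0.103) or LPS library 3 (0.0986). It was lost as well with no filter on low values (0.0970), after median-of-ratios (0.760) or upper-quartile scaling (0.439), and with Saa3 and Fth1 left out (0.191). The single tested chondrocyte gene, Hapln1, had 3.23 ± 2.37 and 5.77 ± 2.62 TPM (adjusted p = 0.194). It passed under quantile normalization (adjusted p = 0.0470) and with the replicate number as a block (adjusted p = 0.0141).

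All 36 tested cell cycle genes fell on TPM as deposited, with a median 3.99 below that of all genes (camera adjusted p = 8.94e-11, adjusted p = 0.124 with an estimated correlation); after median-of-ratios scaling 35 fell and E2f1 (named after its value was seen) rose by 0.17. The mitotic kinase gene Plk1 fell from 98.6 ± 3.97 to 0.443 ± 0.0651 TPM and the ribonucleotide reductase gene Rrm2 from 166 ± 3.64 to 1.54 ± 0.204 TPM. Histone genes summed to 297 ± 5.77 TPM in control and 162 ± 13.7 TPM in LPS libraries (exact permutation p = 0.1, BH-adjusted 0.183), and 11 of 15 tested members fell, or 8 fell and 2 rose after median-of-ratios scaling (camera adjusted p = 0.308).

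Genes of macrophage identity changed in both directions, 10 of 26 up and 15 down, or 16 down adjusted over the list alone, and 12 up and 10 down after median-of-ratios scaling (camera adjusted p = 0.245). Trem2, a lipid-sensing receptor, fell from 1917 ± 116 to 229 ± 5.37 TPM and the inhibitory Fc receptor gene Fcgr2b rose from 36.6 ± 3.77 to 662 ± 20.0 TPM. Of immediate early and heat shock genes 9 of 18 rose, 7 fell and 2 did not pass, or 12 rose and 3 fell after median-of-ratios scaling (camera adjusted p = 0.0174, adjusted p = 0.270 with an estimated correlation). Camera also lost this call with no filter on low values (adjusted p = 0.206) and under quantile normalization (adjusted p = 0.115). Atf3 fell from 156 ± 0.513 to 41.2 ± 0.583 TPM and Ier3 rose from 35.8 ± 4.41 to 183 ± 2.43 TPM. Among markers of other marrow cells, B cell genes summed to 61.3 ± 3.20 TPM in control and 0.887 ± 0.447 TPM in LPS libraries (exact permutation p = 0.1, BH-adjusted 0.183). Nearly all of the control sum was Ighm, which fell from 60.1 ± 3.08 to 0.347 ± 0.211 TPM. T and NK cell genes summed to 2.80 ± 1.01 and 2.63 ± 0.0643 TPM (exact permutation p = 0.9), with Cd247 at 1.65 ± 0.268 and 1.88 ± 0.316 TPM (adjusted p = 0.465, but 0.0241 after median-of-ratios scaling and 0.00533 under quantile normalization). Erythroid and megakaryocyte genes summed to 2.21 ± 0.298 and 0.790 ± 0.139 TPM (exact permutation p = 0.1), and mast cell and basophil genes to 0.453 ± 0.220 and 0.15 ± 0.131 TPM (exact permutation p = 0.2), with 0 tested members in either list. Over the 11 sums of other-cell and quality lists, BH-adjusted values of the exact permutation test lay between 0.183 and 0.900.

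**Figure D3:**
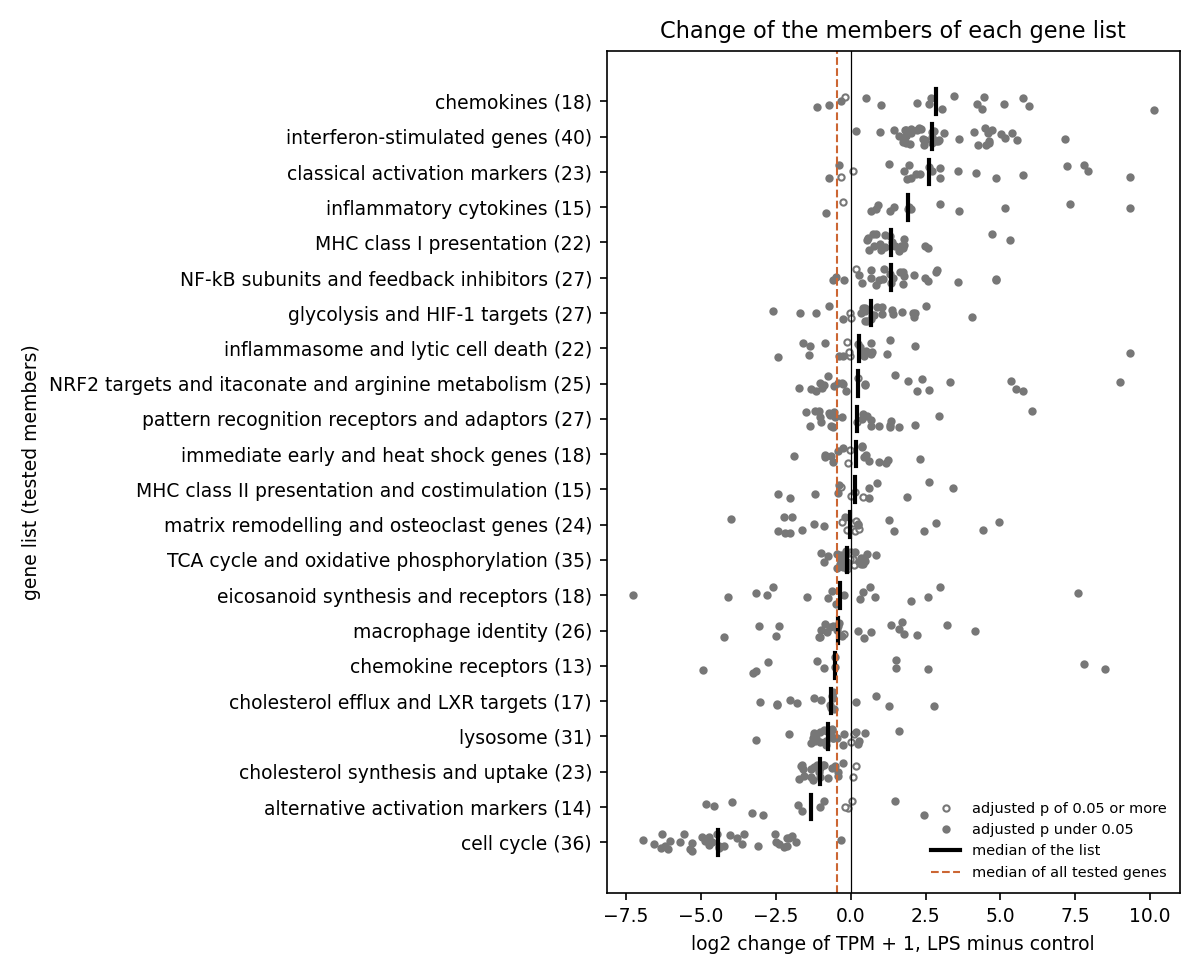
Log2 change of TPM + 1 (LPS minus control, x axis) of every tested member of the biology lists (y axis, number of tested members in brackets); filled points have an adjusted p under 0.05, bars mark list medians and the dashed line the median of all tested genes at −0.44. All 40 interferon-stimulated genes and all 22 class I genes lie above 0 and all 36 cell cycle genes below 0 on TPM as deposited, where E2f1 turns under median-of-ratios scaling.

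Camera with the preset correlation called 13 lists higher and 4 lower. With an estimated correlation 8 of the higher calls held (chemokines, inflammatory cytokines, classical activation, interferon-stimulated genes, NF-kB, class I presentation, the NRF2 and itaconate list and neutrophil markers, adjusted p between 0.0376 and 0.0489) and 0 of the lower ones, with 1 list, cell cycle, lower at an unadjusted p under 0.05. For chemokines the estimated correlation was 0.0097, below the preset 0.01, yet the unadjusted p of camera went from 8.34e-12 to 0.00237. Calls lost with an estimated correlation therefore do not measure correlation alone. Among the lists that lost a call, however, the estimate was above the preset. It ran from 0.015 for class II presentation to 0.51 for ribosomal proteins. For interferon-stimulated genes, which kept their call, it was 0.28. Where the estimate exceeds the preset, the p of camera with the preset correlation may be far too small. Adjusted over the list alone, each list gave the counts printed above for TPM as deposited, apart from the classical activation and macrophage identity lists where both are given. The adjusted p-values rest on the spread among 3 libraries per group, which may be technical, and a shift shared by most genes cannot be separated from the fixed total of TPM.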

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

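Rescaling without Saa3 and Fth1 was chosen only after the result was seen. The excess of lower over higher calls depended on scaling. Higher calls made up 21.4% of calls on TPM as deposited. They made up 49.9% after median-of-ratios scaling and 48.6% under quantile normalization, where almost no excess was left and the median is centred by construction. Median-of-ratios scaling called 4167 genes higher and 4181 lower (1360 and 1471 at least 2-fold), upper-quartile scaling 3543 and 4875 (1174 and 1687 at least 2-fold) and quantile normalization 4029 and 4257 (1310 and 1432 at least 2-fold). Rescaling without Saa3 and Fth1 called 2938 higher and 5784 lower. These scalings set another reference level by construction. Camera with an estimated correlation called 8 lists higher and 0 lower, and fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 14 higher and 12 lower. Leaving out each library in turn gave 1899 to 2012 genes higher and 7051 to 7260 lower; without control library 2, which stood apart, it gave 2012 and 7223.

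Among the named genes, 1418 of the values under other settings kept their direction and side of the threshold, 11 lost the call, 7 gained one and 4 turned. Bgn went from −0.44 to 0.16 under quantile normalization, and Itgax, called under none of these, from −0.31 to 0.14 after median-of-ratios scaling, 0.033 after upper-quartile scaling and 0.26 under quantile normalization. These scalings set another reference level. Among the lists, 485 values kept both, 6 lost a call, 8 gained one and 10 turned in their median relative to all genes or in the direction of camera. With no filter on low values that median was −0.093 for pattern recognition, which camera still called higher, −0.022 for the TCA cycle list, −0.14 for eicosanoids, −0.30 for macrophage identity and −0.070 for stromal markers. The median of all genes was −0.10 there. Camera turned for chemokine receptors after median-of-ratios scaling (median −0.033) and quantile normalization (−0.29), and quantile normalization gave −0.14 for eicosanoids and for macrophage identity. The latter also turned without LPS library 3, with −0.0058 to 0.066 over the libraries left out. Apart from pattern recognition, camera called none of these lists on TPM as deposited or where it turned, and the cause was not tested. With the replicate number as a block, 1993 genes were called higher and 7304 lower. Camera called 13 lists higher and 4 lower as without it, while Hapln1 and Itgax passed the threshold (adjusted p = 0.0141 and 0.0381). Deviations of same-numbered libraries from their group means correlated at 0.0744, −0.151 and 0.0765, and not every library correlated best with its own number, so the numbers are not read as pairs. The depth behind TPM is unknown and limits what can be said of low genes.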

Other observations

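The tests of annotated terms, of Saa3 and Fth1, of the fall of most mRNAs, of neutrophil transcripts, of scaling for the ferritin genes and of other splits were chosen only after the results they bear on were seen; the test of gene length and that of summed ferritin rows were set before their values were computed, the latter with the changes of Fth1 and Ftl1 already known. Genes named below outside the rule for named genes were chosen after their values were seen.

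Terms annotated in the deposited table, with at least 10 and at most 300 tested members, were compared by camera with the preset correlation. Of 235 KEGG maps over 4255 annotated tested genes, 18 were called higher and 8 lower, and of 1430 biological processes over 10378 genes 86 and 29; with an estimated correlation 0 were called in either source, where 8 maps higher and 3 lower, and 52 processes higher and 8 lower, had an unadjusted p under 0.05. With an estimated correlation the smallest unadjusted p of camera among the gene lists was 0.00237, for chemokines. Such a p cannot by itself pass an adjustment over 235 or 1430 terms, so the 0 calls alone cannot decide about the terms. In both sources the terms with an unadjusted p under 0.05, both directions together, made up a share below 0.05. Chance alone gives about that share, so the calls of terms rest on the preset correlation. Proteasome genes rose in 29 of 43 tested members and fell in 3 (median 0.71 above all genes, camera adjusted p = 7.80e-09, adjusted p = 0.651 with an estimated correlation). They include subunits of the standard proteasome, such as Psma6, which rose from 122 ± 3.63 to 271 ± 7.50 TPM, and Psmb5, from 159 ± 16 to 363 ± 17.9 TPM, as well as the immunoproteasome subunits Psmb8 and Psmb10 of the class I list. Mismatch repair genes, many of which also serve replication, fell in 21 of 22 tested members (median 1.04 below all genes, camera adjusted p = 0.00240, adjusted p = 0.651 with an estimated correlation), among them Msh6, from 16.2 ± 0.342 to 4.88 ± 0.202 TPM, and the ligase gene Lig1, from 91.5 ± 1.74 to 7.02 ± 0.718 TPM.

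Annotated terms of iron were not called by camera. Of 32 tested genes of cellular iron ion homeostasis 6 rose and 23 fell (adjusted p = 0.945), and of 17 of iron ion homeostasis 7 rose and 6 fell (adjusted p = 0.0571). Single genes, picked for their values, had limma adjusted p-values between 4.72e-08 and 1.61e-05 and stand for no group. Fth1, the ferritin heavy chain, rose from 20156 ± 964 to 76204 ± 1312 TPM, while Ftl1, the light chain, fell from 27835 ± 664 to 13551 ± 51.7 TPM. Slc40a1, the iron exporter ferroportin, fell from 92.4 ± 0.742 to 1.41 ± 0.431 TPM, the transferrin receptor gene Tfrc fell from 29.6 ± 1.61 to 14.7 ± 0.938 TPM, and Hmox1, which frees iron from haem, rose from 499 ± 17.9 to 2579 ± 145 TPM. These 5 genes kept their direction after median-of-ratios scaling. That scaling can only raise a change here, so it tested the falls of Ftl1, Slc40a1 and Tfrc and not the rises of Fth1 and Hmox1. Ighm had 60.1 ± 3.08 TPM in control libraries, while the B cell gene with the next highest level, Cd79b, had 0.970 TPM.

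More genes were called lower than higher on TPM as deposited, with a median change of −0.44. With Saa3 and Fth1 left out and TPM rescaled the median was −0.22 (95% interval over genes −0.24 to −0.21). The share of that pair alone does not account for the excess, though it moved the median. The interval treats genes as independent and does not measure the spread between libraries. With genes parted by length into 3 groups of nearly equal size, the median was −0.34 in the shortest, −0.48 in the middle and −0.51 in the longest group, which argues against gene length as the whole cause. A fall of most mRNAs per cell may be a further source and cannot be told apart from the fixed total of TPM: median-of-ratios scaling made 49.9% of calls higher, but it centres the median by construction. Of the 10 splits of the 6 libraries, 1, the labelled one, called as many genes (9469, against at most 1 in the others). The 10 splits are too few for a share under 0.05. The others also mix LPS and control libraries in each part, so the difference between groups enters their spread and keeps calls few. Their counts therefore do not measure how many of the 9469 calls are false.

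Neutrophil list members were higher in LPS libraries, and neutrophils in the LPS cultures could be a source. Of the 15 listed genes, 5 were tested, Mmp8 and Cxcr2 also stand in other lists, and 10 stayed under 1 TPM in the mean of the LPS libraries, among them S100a9 at 0.543 TPM beside S100a8 at 79.9 TPM, and Ly6g, Prtn3 and Retnlg were listed at 0 in all 3. Neutrophils would bring S100a9 together with S100a8, and Ly6g and Retnlg with them, so the values of these genes argue against neutrophils. Listed genes such as Prtn3 need not be expressed at every stage of neutrophil maturation, so the count of 10 by itself adds less. That macrophages express Lcn2, S100a8 and Camp themselves after LPS remains a hypothesis that these libraries do not test.

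Ferritin heavy and light chain transcripts moved apart. Reads moved between the genes and their pseudogene copies could produce such a pattern, but summed over all 17 rows described as heavy chain TPM rose by 1.92 on the log2 scale, and over all 24 light chain rows it changed by −1.04, with no overlap between groups. Ftl1 changed by −1.04 on TPM as deposited, −0.54 (SE 0.07) after median-of-ratios scaling, −0.66 after upper-quartile scaling and −1.67 under quantile normalization. Fth1 changed by 1.92, 2.42, 2.30 and 1.38, so the sign of each chain did not depend on the choice among these scalings. Median-of-ratios and upper-quartile scaling divide a library by 1 factor and shift both chains alike. They therefore could not test whether the chains moved apart. Both shifts are upward here, so the rise of Fth1 could not turn under these scalings. An opposite regulation of both chains by LPS is therefore a hypothesis, found and tested on the same libraries.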
